A study of Mus musculus with 2 samples.

How the data were processed

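Histone H3 trimethylated at lysine 4 (H3K4me3), a mark found at active and poised promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in facial prominences of mouse embryos at embryonic day 11.5. Per the labels, the embryos were of strain B6NCrl and both sexes, the laboratories belonged to the ENCODE project, and there were 2 biological replicates. Replicate 1 was a pool of tissue from 109 embryos and replicate 2 a pool from 88 embryos, and library fragments were selected at 300 to 500 bp. Both replicates formed 1 group, so there was no contrast between conditions and no pairing of samples across groups.

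The deposited files were 4 peak lists in narrowPeak format on the mm10 build, per the file notes. A list was called on each replicate alone, 1 on both replicates pooled, and 1 was a list of replicated peaks derived from the other lists. The rule for replication, the aligner, the peak caller and its thresholds were not given in the sources used here. All 20789 replicated peaks were identical in position to a peak of the pooled list, so replicated peaks carry boundaries set on pooled reads. The file notes show that the list of replicate 1 was derived from its alignments and a pair of further files, and that of replicate 2 from its alignments and only 1 of these. Their role is not stated, so a control shared by the replicates is possible, and the replicates' lists may therefore differ in background as well as in biology.

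Per the file notes, the values of each peak were a signal, which is the authors' enrichment of the peak, and a p-value and q-value deposited as −log10 values. What the enrichment is relative to is not given in the sources used here. It is the authors' own value. It was used to describe and rank peaks within a list, and to compare gene lists by permutation tests within the replicated list. Between the replicates it entered only a rank correlation. The lowest −log10 p over the deposited lists was 2.02. Read counts are not part of these files, so sequencing depth is unknown and no interval or detection limit for reads could be given. Confidence intervals are exact Clopper-Pearson intervals at 95% and cover the counting of genes or peaks only.

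Gene positions came from GENCODE release M21, whose build is the same as mm10, and sequence from the RefSeq genome of that build. No peak ended beyond the end of its chromosome on the 21 chromosomes with peaks. Coordinates are 1-based on mm10. A protein-coding gene counted as marked when a peak overlapped the 1 kb either side of a transcription start site (TSS) of any of its protein-coding transcripts, among 21943 genes. Peaks within 1 kb of each other were merged into domains, and a gene's domain was the widest that met this window. A domain shared by neighbouring genes was counted for each of them. The enrichment of a domain was the highest among its peaks, so a stronger peak in another, narrower domain of the gene was not counted. Peaks of the replicates counted as shared when they overlapped by at least 1 base; counts from Python were the same as those from bedtools 2.31.1. The ratio of observed to expected CpG dinucleotides was computed for the 1 kb either side of each gene's 5′ end and was available for 99.5% of genes. The marked domain can lie away from this end, as at Mef2c, Esrrb and Set, and the ratio then describes another part of the gene.

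Before the data were examined, 18 gene lists were written from general knowledge, for facial mesenchyme, surface ectoderm, Hox genes, signalling, orofacial clefts, cell cycle and housekeeping, and for other cell types and organs that should be rare or missing in the tissue. The symbol Ahsp was not in the annotation, and Tf was matched as Trf. Of the 34 cleft genes, 10 were also in the signalling list, 6 in the facial mesenchyme list and 3 in the ectoderm list. The share of marked members was compared with all other protein-coding genes by 2-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over the 18 lists. The median domain width of marked members was compared with 100000 random lists of as many marked genes in a 2-sided permutation test, adjusted over the 14 lists with at least 5 marked members. The smallest p these permutations can give is 2.0e-05, which is 4.7e-05 after adjustment. The 3 comparisons between pairs of gene groups used 100000 permutations of group membership, with unmarked genes at width 0, and Fisher's exact tests, each adjusted over the 3 pairs; their smallest p is 1.0e-05. Genes and peaks, not embryos, are the units of all these tests, so each p describes the lists of peaks and no p across the 2 replicates can be given. The tests took genes as independent, although neighbours in a cluster can share a domain. Each value was also taken from each replicate's own list.

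Genes were named by a rule set before the data were examined. It named the genes at the 15 widest domains and at the 5 peaks of highest enrichment, the 2 widest and the first 2 unmarked members of each list in alphabetical order, and, for the facial mesenchyme, ectoderm, Hox and signalling lists, the 5 widest and up to 6 unmarked members. It also named the genes at the 3 widest peaks found in 1 replicate alone. Other genes named were chosen after their values were seen.

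The alternatives tried were −log10 q of at least 2 or 10, overlap of 50% of both peaks, merging before the overlap, windows of 500 bp or 2.5 kb, the gene's 5′ end only, each replicate's list alone, the pooled list, merging only where peaks touch or within 2.5 kb, and random lists matched on CpG ratio or gene length in 10 strata. A logistic model with CpG ratio as covariate, with a likelihood-ratio test over the 21843 genes with a ratio, was the alternative for shares. Another 2 alternatives were added after seeing the data: each domain counted once, and replicated peaks that overlapped a peak of both replicates.

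The statistics were tested on simulated data. In 200 simulated lists of 30 genes among 21943, lists with no effect were called in 4.00% for the share and 3.00% for the width. Lists marked at 95% were called in 99.0%, and lists with domains 2 times as wide in 100%. Marks and widths were drawn independently for each gene, so these rates do not cover neighbouring genes that share a domain. The overlap procedure classed 100.0% of 20789 peaks as simulated. There, matched peaks were only slightly shifted and the others were put on a made-up chromosome. That outcome was fixed in advance and checks the code only. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.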

Results

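H3K4me3 was mapped in the facial prominences of the mouse embryo at embryonic day 11.5, the paired and midline swellings of neural crest mesenchyme and covering ectoderm that form the face. The 2 biological replicates, pools of 109 and 88 embryos, formed a single group. The list of replicate 1 held 24981 peaks over 29.9 Mb with a median width of 1005 bp, and that of replicate 2 held 24593 peaks over 26.9 Mb with a median width of 908 bp. The authors' list of replicated peaks held 20789 peaks over 30.1 Mb, with a median width of 1301 bp and a median enrichment of 20.4. The narrowest 10% of its peaks were at most 367 bp wide, the widest 10% at least 2648 bp, and the widest 16309 bp. Of the replicated peaks, 19015 (91.5%) overlapped a peak in both replicates' own lists. A gene marked in the replicated list therefore need not have a peak in each replicate's list. Sequencing depth is unknown, since the files hold no read counts.

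The first question was whether the replicates named the same promoters. A total of 13907 protein-coding genes were marked in both replicates, against 192 in replicate 1 only and 105 in replicate 2 only. Nr2f2, an orphan nuclear receptor gene, had the widest domain, at 22971 bp in replicate 1 and 24776 bp in replicate 2. Tbx2, a T-box repressor gene, had domains of 16290 and 16218 bp. Of the peaks, 80.7% in replicate 1 and 87.8% in replicate 2 overlapped a peak of the other, and the shared bases made up 0.787 of the union (25.0 of 31.8 Mb). Across overlapping peaks, which are not independent replicates, the Spearman correlation was 0.848 for width and 0.891 for enrichment, and across genes it was 0.911 for domain width. Domains were somewhat narrower in replicate 2, with a median ratio to replicate 1 of 0.926. With overlap of 50% of both peaks required, the shares were 70.9% and 72.0%.

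**Figure D1:**
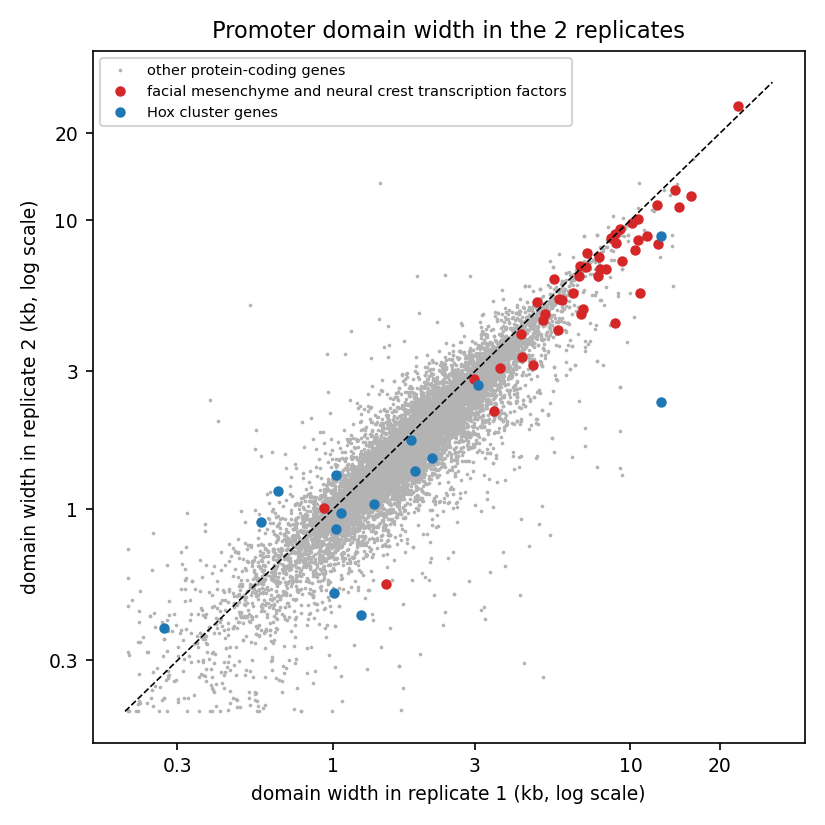
Width of the promoter domain of each protein-coding gene marked in both replicates, in replicate 1 (x axis) and replicate 2 (y axis), in kb on log scales; the dashed line is equality. Most genes lie near the line, facial mesenchyme factors (red) at its wide end up to Nr2f2, while Hoxa1 (blue, 12698 bp in replicate 1) lies far below it at 2355 bp in replicate 2.

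Peaks in a single replicate's list were short and weak. Replicate 1 had 4823 such peaks (19.3%), with a median width of 247 bp against 1285 bp for its shared peaks and a median enrichment of 3.56 against 20.9. Replicate 2 had 3004 (12.2%), with a median width of 217 bp against 1073 bp and a median enrichment of 3.39 against 15.4. Only 36.3% and 32.4% of them lay within 1 kb of a TSS, against 80.9% and 79.4% of shared peaks. The 3 widest in replicate 1 lay within the genes Eml2 (963 bp), Kif26b (947 bp) and Zic4 (929 bp), and none had a TSS within 1 kb. Of the 3 widest in replicate 2, 1 lay in no gene (684 bp; chromosome 14, 12341336 to 12342019), 1 in Prrc2b (680 bp) and 1 in Sox1 and its overlapping transcript Sox1ot (652 bp). Only 34 of them in replicate 1 and 1 in replicate 2 had −log10 q of at least 10.

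Most replicated peaks were promoter peaks. Of the 20789, 16300 (78.4%, 95% Clopper-Pearson interval 77.8 to 79.0) overlapped the 1 kb either side of an annotated TSS, and these had a median width of 1542 bp and a median enrichment of 27.7. The 3002 peaks at 1 to 10 kb from a TSS (14.4%) had medians of 513 bp and 4.81, and the 1487 peaks farther away (7.15%) had medians of 558 bp and 5.60. The mark was present at 14039 of 21943 protein-coding genes (64.0%), with 14099 in the list of replicate 1 and 14012 in that of replicate 2. The median domain of a marked gene was 1871 bp wide, and the widest 5% began at 4162 bp.

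Developmental transcription factors held most of the widest domains. The domain of Nr2f2 spanned 22997 bp on chromosome 7 (70347834 to 70370830), and the adjacent homeobox genes Dlx1 and Dlx2, which pattern the branchial arches, shared 19948 bp on chromosome 2 (71527262 to 71547209). Tbx2 followed with 16309 bp in a single peak (chromosome 11, 85828937 to 85845245), then Nr2f1 with 15226 bp, Six2 with 14639 bp and, near it on chromosome 17, Six3 with 14454 bp. Irx5 (13883 bp), Meis2 (13301 bp), Dlx6 (12420 bp) and Pitx1 (12388 bp) were of the same class, as was Gata3, which shared 12304 bp with the annotated coding genes 4930412O13Rik and 9230102O04Rik. The remainder were Ptch1, the receptor for hedgehog ligands (12644 bp), Tnrc18 (13194 bp), and chromatin enzymes: Kdm6b, a histone H3 lysine 27 demethylase (12942 bp), and Setd1b, a histone H3 lysine 4 methyltransferase, which shared 13564 bp with Rhof. The widths of several of these domains depended on how separate peaks joined. For Six3 the replicates gave 13899 and 5913 bp (mean 9906 ± 5647 bp, SD, n = 2), and for Rhof 1434 and 13472 bp. In both replicates' own lists the domain of Dlx1 and Dlx2 was split, with 10575 and 10078 bp at Dlx1 and 8271 and 6779 bp at Dlx2. Pitx1 had 7112 and 6868 bp and Gata3 7943 and 5296 bp, while 4930412O13Rik and 9230102O04Rik lay in a separate domain of 4234 and 3794 bp.

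The highest enrichment was found elsewhere. The 5 strongest peaks lay at Pgs1 (enrichment 75.2), Sfpq (74.9), Set (74.7), Npepps (73.2) and Arid1a (73.2). These are broadly expressed genes for a lipid synthesis enzyme, a splicing factor, a histone chaperone, an aminopeptidase and a chromatin remodelling subunit. Their peaks were 1693 bp wide at Pgs1, 2333 bp at Npepps, 3259 bp at Set, 4698 bp at Sfpq and 5117 bp at Arid1a. Among the 15 widest domains the enrichment ran from 10.7 at the Gata3 domain to 60.1 at Tnrc18. Six3 (14.5) and Pitx1 (18.8) were also low, and the other 12 had 30.2 or more.

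All 44 listed transcription factors of facial mesenchyme and neural crest were marked, and their median domain was several times as wide as that of other marked genes. The share of 100% (interval 92.0 to 100) compared with 63.9% of other genes (Fisher's exact test, adjusted p = 3.1e-08), and it was 44 of 44 in each replicate. From the CpG ratio of these promoters 91.2% would be expected, which leaves a difference of 8.8 points (likelihood-ratio test, n = 21843 genes, adjusted p = 5.9e-04). The median domain was 7412 bp, or 3.96 times the 1873 bp of random lists, whose central 95% ran from 1581 to 2197 bp (permutation test, adjusted p = 4.7e-05). The replicates' own medians were 7462 and 6574 bp (mean 7018 ± 628 bp, SD, n = 2). Of the 44, 38 were within the widest 5% of marked genes. The widest in the replicated list were Nr2f2 (mean of replicates 23874 ± 1276 bp, SD, n = 2), Dlx1 (10326 ± 351 bp), Dlx2 (7525 ± 1055 bp), Nr2f1 (14058 ± 2758 bp) and Six2 (12839 ± 2435 bp). Msx1, a homeobox gene needed for palate and tooth formation, had 11539 bp (11786 ± 668 bp), more than Dlx1 and Dlx2 by the replicates' means. The narrowest, named after their values were seen, were Tbx22 (980 bp) and Hand1 (588 bp; replicates 1506 and 553 bp). With peaks merged only where they touched, the median was 4835 bp (permutation test, adjusted p = 9.3e-05). The median enrichment of these domains, 32.2, did not differ from the 34.2 of random lists of marked genes (permutation test, unadjusted p = 0.573). It was below the 40.8 of random lists matched on width in 10 strata (central 95% 34.0 to 46.6, permutation test, adjusted p = 0.0195). The widest stratum has no upper bound, and 38 of the 44 genes lay in the widest 5%, which began at 4162 bp. The matched lists can therefore be narrower than this list, so whether its enrichment is low at equal width was not decided.

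**Figure D2:**
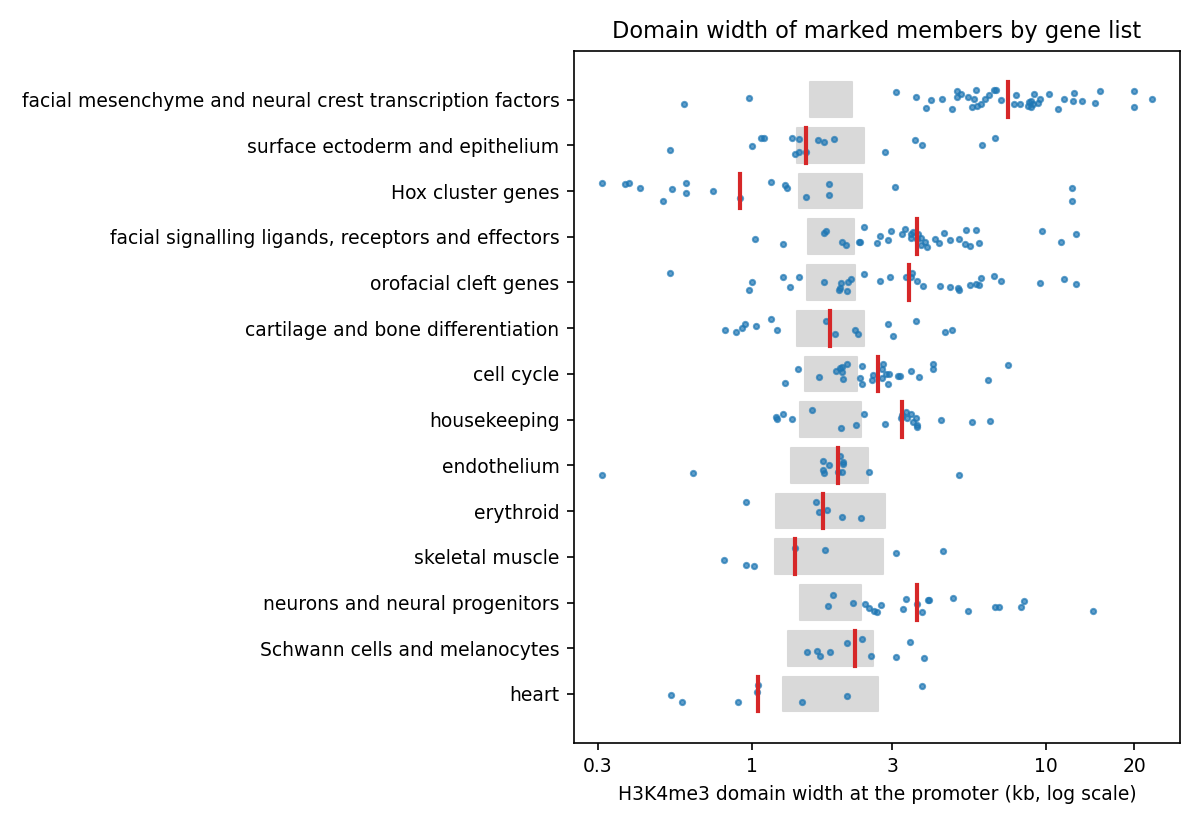
Width of the promoter domain of each marked member (points, kb, log scale) in the 14 gene lists with at least 5 marked members; red bars are list medians and grey boxes the central 95% of medians of random lists of the same size. Facial mesenchyme factors have a median of 7412 bp, far above their box, and Hox genes one of 912 bp, below theirs.

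The listed genes for facial signalling and for orofacial clefts were likewise all marked, with wide domains. For signalling, 37 of 37 members were marked (Fisher's exact test, adjusted p = 4.1e-07), with a median domain of 3637 bp against 1871 bp in random lists (permutation test, adjusted p = 4.7e-05). The widest were Ptch1 (replicates 12546 and 7461 bp), Wnt5a (11243 bp), Pdgfra, a receptor of neural crest mesenchyme (9721 bp; replicates 9580 ± 31.8 bp, SD, n = 2), Bmp4 (5935 bp) and its antagonist Nog (5809 bp). The ligands made mainly by epithelium also had the mark, named after their values were seen: Shh had 4211 bp (3801 bp in replicate 1 but 639 bp in replicate 2), Fgf8 2332 bp, Wnt9b 1277 bp and Edn1 1029 bp. For clefts, 34 of 34 members were marked (adjusted p = 1.9e-06) with a median of 3416 bp (permutation test, adjusted p = 4.7e-05), led by Ptch1 and Msx1. Both counts were the same in each replicate. Given promoter CpG ratio, 90.5% of the signalling genes would be expected to be marked (likelihood-ratio test, n = 21843 genes, adjusted p = 0.00492) and 88.5% of the cleft genes (likelihood-ratio test, n = 21843 genes, adjusted p = 9.1e-04). The cleft list is not independent of the others, since 19 of its genes were in another list.

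The next comparison set Hox genes, which are not expressed in the neural crest of the face, against the facial mesenchyme factors. Only 19 of 39 Hox genes were marked (48.7%, interval 32.4 to 65.2), against 44 of 44 facial factors, a difference of -51.3 percentage points (Fisher's exact test, adjusted p = 2.5e-08). With unmarked genes at 0, the median domain was 0 bp for Hox genes and 7412 bp for facial factors (permutation test, adjusted p = 1.5e-05). The marked Hox genes had a median domain of 912 bp, or 0.487 times that of random lists (adjusted p = 4.7e-05, permutation test), and a median enrichment of 8.0. Most had short domains, with the exception of Hoxa1 and Hoxa2, which shared 12300 bp at the 3′ end of the HoxA cluster (chromosome 6, 52158328 to 52170627), and Hoxb2 with 3066 bp. Hoxa4 (1839 bp) and Hoxa5 (1833 bp) came next. Hoxa3, Hoxa6, Hoxa9, Hoxa10, Hoxa11 and Hoxb1 were among the 20 that were not marked, although Hoxa10 had a peak of 439 bp in replicate 1. Unmarked genes could still hold peaks farther than 1 kb from their annotated coding TSSs, as 4 of the 20 did, named after their values were seen: Hoxa3, with 11 replicated peaks within an annotated span that also includes Hoxa4 and Hoxa5, Hoxb3 with 4, and Hoxc6 and Hoxc9 with 1 each. The replicates differed in the number of marked Hox genes, with 25 in replicate 1 and 16 in replicate 2, and for Hoxa1 the widths were 12698 and 2355 bp. Hoxb6, Hoxb7, Hoxd10 and Hoxd11, marked in the replicated list, had no domain in the list of replicate 2. Against all other genes the Hox share did not differ (64.0% of others; Fisher's exact test, adjusted p = 0.0896), but given the CpG content of Hox promoters 88.6% would be expected, a difference of -39.9 points (likelihood-ratio test, n = 21843 genes, adjusted p = 8.9e-16). The comparison with all other genes varied with the list, from -22.9 points in replicate 2 (Fisher's exact test, adjusted p = 0.00678) through -0.2 in replicate 1 to 2.1 in the pooled list with 26 marked. With −log10 q of at least 10 the difference was -33.5 points (Fisher's exact test, adjusted p = 7.8e-05), and the median width, 1316 bp, no longer differed from random lists (permutation test, adjusted p = 0.0745).

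**Figure D3:**
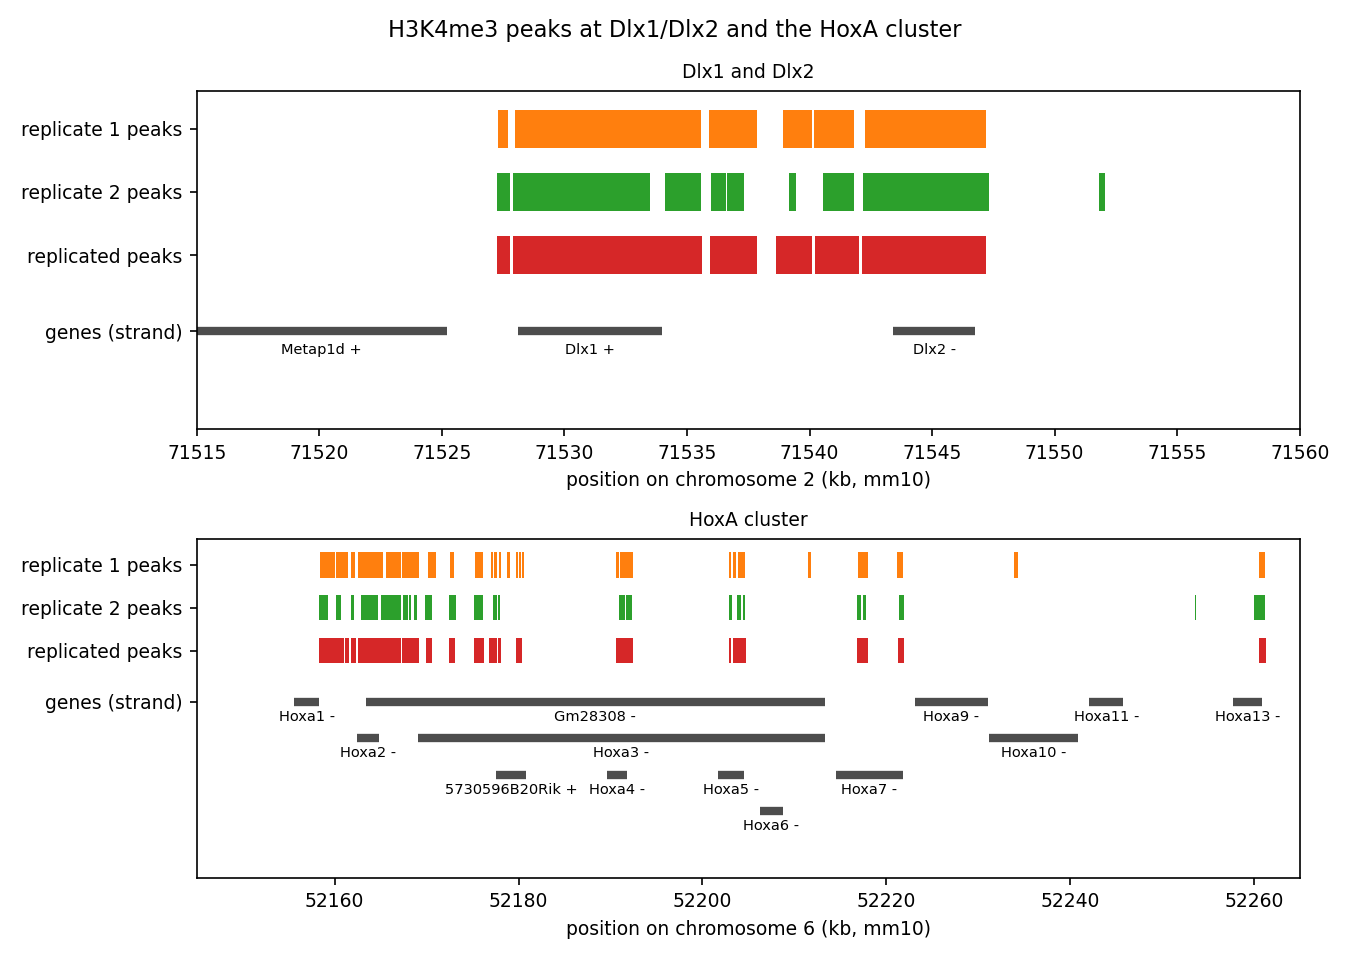
Peaks of replicate 1 (orange), replicate 2 (green) and the replicated list (red) with protein-coding genes and their strand (grey), by position in kb on mm10, at Dlx1 and Dlx2 on chromosome 2 and across the HoxA cluster on chromosome 6; the panels have different scales. Replicated peaks cover 92.7% of the 19948 bp of Dlx1 and Dlx2, against 88.7% for replicate 1 and 77.6% for replicate 2, whose longest gaps are 1053 and 1836 bp, whereas in the HoxA cluster they crowd around Hoxa1 and Hoxa2 and are short and scattered toward Hoxa13.

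Within the Hox clusters, the median domain was wider for anterior than for posterior genes when unmarked genes counted as 0. Of paralogue groups 1 to 4, 8 of 12 genes were marked, with a median domain of 948 bp when unmarked genes were set to 0. Of groups 9 to 13, 5 of 16 were marked and the median was 0 bp. The unmarked genes with peaks elsewhere in the gene were Hoxa3 and Hoxb3 of the anterior groups and Hoxc9 of the posterior ones. The widths differed (permutation test, adjusted p = 0.00153), whereas the shares of 66.7% and 31.2% did not pass Fisher's exact test (adjusted p = 0.125). Most posterior genes were unmarked, so their median of 0 bp reflects the share as well as the width. The tests took genes as independent, although Hoxa1 and Hoxa2 shared 1 domain. With only the 5′ end of each gene used as its TSS, the difference of medians was 499 bp and did not pass the permutation test (adjusted p = 0.0546), and with −log10 q of at least 10 it was 421 bp (adjusted p = 0.0230, permutation test). The shares differed among replicated peaks that overlapped a peak of both replicates (47.9 points, Fisher's exact test, adjusted p = 0.0189).

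Genes of the surface ectoderm carried the mark over shorter stretches than the mesenchymal factors. The ectodermal list also holds genes that are not transcription factors, such as keratins, so tissue and gene class were not separated. Of 22 genes, 17 were marked (77.3%, interval 54.6 to 92.2), a share that did not differ from that of other genes (Fisher's exact test, adjusted p = 0.320). With unmarked genes at 0, the median domain was 1426 bp against 7412 bp for facial mesenchyme factors (permutation test, adjusted p = 1.5e-05), and the share of the facial factors was 22.7 points higher (Fisher's exact test, adjusted p = 0.00442). Tfap2c (6724 bp; replicates 5611 and 2813 bp) and Pitx2 (6070 bp) had the widest domains. They were followed by the epithelial splicing regulators Esrp1 (3801 bp) and Esrp2 (3600 bp), and by Grhl2 (2848 bp; replicates 2722 ± 14.8 bp, SD, n = 2). The 5 unmarked genes were the keratins Krt5, Krt14 and Krt15 of stratified epithelium, Sfn, and Trp63, the gene of the epidermal regulator p63. The difference of medians, 5986 bp, was 3410 bp with peaks merged only where they touched (permutation test, adjusted p = 1.5e-05). The difference in shares was lost when only 5′ ends were used (Fisher's exact test, adjusted p = 0.121), and the ectodermal median of marked genes, 1530 bp, was within the range of random lists except in the list of replicate 2 alone (1240 bp, permutation test, adjusted p = 0.0384).

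The lists of cell cycle and housekeeping genes were marked without exception. All 28 cell cycle genes had the mark (Fisher's exact test, adjusted p = 9.9e-06), with a median domain of 2678 bp (permutation test, adjusted p = 1.0e-03), and the cyclin D genes Ccnd2 (7460 bp) and Ccnd1 (6341 bp) were widest. All 21 housekeeping genes were marked (Fisher's exact test, adjusted p = 2.3e-04), with a median of 3239 bp (permutation test, adjusted p = 4.7e-05) and a median enrichment of 54.1. The widest were Rps18 (6451 bp; replicates 6340 and 3663 bp), whose domain also met the promoters of B3galt4 and Vps52, and Tubb5 (5604 bp). In a logistic model with promoter CpG ratio as covariate, the share of cell cycle genes no longer stood apart (likelihood-ratio test, n = 21843 genes, adjusted p = 0.260), and that of housekeeping genes was 11.4 points above the 88.6% expected (likelihood-ratio test, n = 21843 genes, adjusted p = 0.00857).

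Among the lists for cells that should be rare or missing in the tissue, neurons and neural progenitors alone had both a high share and wide domains. The list holds many transcription factors, such as Six3 and Sox2, so tissue and gene class were not separated. Of 22 genes, 21 were marked (95.5%, interval 77.2 to 99.9; Fisher's exact test, adjusted p = 0.00220), 22 in replicate 1 and 21 in replicate 2. The exception was Dcx, a microtubule protein gene of young neurons, with 248 bp in replicate 1 only. Their median domain was 3654 bp against 1871 bp in random lists (permutation test, adjusted p = 4.7e-05), led by Six3 and Sox2 (8416 bp; replicates 8048 ± 1114 bp, SD, n = 2), yet their median enrichment was 12.8. The width did not differ when peaks were merged only where they touched (2137 bp, permutation test, adjusted p = 0.179). The share did not differ with −log10 q of at least 10 (Fisher's exact test, adjusted p = 0.240), nor did it with CpG ratio as covariate (likelihood-ratio test, n = 21843 genes, adjusted p = 0.0920).

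Skeletal, vascular and glial lists were marked in part. Among genes of cartilage and bone differentiation, 16 of 26 were marked (Fisher's exact test, adjusted p = 0.839) with a median domain of 1850 bp, among them Col2a1, the main cartilage collagen (4813 bp), and Sox6 (4551 bp), whereas the late genes Bglap and Col10a1 were not. With peaks merged only where they touched, the median of this list was 1200 bp and lay below random lists (permutation test, adjusted p = 0.00990). Among endothelial genes, 13 of 18 were marked (Fisher's exact test, adjusted p = 0.662), with Fli1 at 5051 bp and Kdr at 2501 bp (replicates 2134 and 1442 bp), and Cdh5 and Pecam1 unmarked. Emcn, counted among the 13 with 309 bp, had no domain in either replicate's own list. Of 17 Schwann cell and melanocyte genes, 10 were marked (Fisher's exact test, adjusted p = 0.662), with Egr2 at 3860 bp and Erbb3 at 3441 bp (replicates 3309 and 1822 bp), and the melanocyte genes Dct and Mlana unmarked. The domains of 2 of the 10 marked genes also met the promoter of another coding gene. The median widths of the endothelial (1971 bp, adjusted p = 0.812) and Schwann and melanocyte lists (2242 bp, adjusted p = 0.347) did not differ from random lists in permutation tests.

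Blood and muscle lists were marked less often than other genes. Of 19 erythroid genes, 6 were marked (31.6%; Fisher's exact test, adjusted p = 0.00979), with Epor (2360 bp) and Tfrc (2033 bp) widest and Alas2 and Epb42 unmarked. Of 20 leukocyte genes only Fcgr3 was marked, by a peak of 392 bp (Fisher's exact test, adjusted p = 2.9e-07), and Adgre1 and Aif1 were among the 19 that were not. Of 21 skeletal muscle genes, 7 were marked (33.3%; Fisher's exact test, adjusted p = 0.00861), and the muscle actin genes Acta1 and Actc1 were not. The widest, at Mylpf (4471 bp), also met the promoter of Tbc1d10b, and the next was at Mef2c (3100 bp). The median widths of erythroid (1748 bp, adjusted p = 0.812) and muscle genes (1401 bp, adjusted p = 0.245) did not differ from random lists in permutation tests. The erythroid share did not stand apart with CpG ratio as covariate (likelihood-ratio test, n = 21843 genes, adjusted p = 0.839). From the CpG ratio 28.4% of leukocyte genes would be expected to be marked, a difference of -23.4 points (likelihood-ratio test, n = 21843 genes, adjusted p = 0.00154), and 52.5% of muscle genes, a difference of -19.2 points (likelihood-ratio test, n = 21843 genes, adjusted p = 0.0279). The muscle share did not differ with a window of 2.5 kb (Fisher's exact test, adjusted p = 0.164), and its median width was then 1102 bp, below random lists (permutation test, adjusted p = 0.00805), as it was with 5′ ends only (1042 bp, adjusted p = 0.0238).

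Liver genes, germ line and pluripotency genes and olfactory receptor genes were rarely marked, whereas the share of heart genes did not differ from that of other genes. Of 20 liver genes, Rbp4 (1074 bp) and Trf (326 bp, in replicate 1 but not in replicate 2) were marked, and Afp and Ahsg were among the 18 that were not (Fisher's exact test, adjusted p = 2.2e-06). The domain of Trf also met the promoter of Gm20425. The liver share of 10% compared with 30.0% expected from promoter CpG ratio (likelihood-ratio test, n = 21843 genes, adjusted p = 0.0207). Of 20 germ line and pluripotency genes, Esrrb (1408 bp) and Dazl (835 bp) were marked, and Ddx4 and Dnd1 were among the 18 that were not (adjusted p = 2.2e-06, Fisher's exact test). The germ line share of 10% compared with 71.6% expected from the CpG ratio of these promoters (likelihood-ratio test, n = 21843 genes, adjusted p = 9.9e-14). Of 1134 olfactory receptor genes only Olfr94 was marked (0.0882%, interval 0.00223 to 0.490; chromosome 17, 37196786 to 37197831), against 67.5% of other genes, and the first unmarked were Olfr1 and Olfr10. With CpG ratio as covariate the share expected was 7.56% (likelihood-ratio test, n = 21843 genes, adjusted p = 3.7e-41). Of 17 heart genes, 8 were marked (47.1%, Fisher's exact test, adjusted p = 0.263) and the cardiac myosin genes Myh6 and Myh7 were not. Tnni3, counted among the 8 with 533 bp, had no domain in either replicate's own list. The widest domains in this list, at Myl3 (3806 bp) and Myl4 (2117 bp), also met the promoters of Pth1r and Cdc27. The median heart domain was 1047 bp against 1876 bp in random lists (permutation test, adjusted p = 0.00829), a difference lost with −log10 q of at least 10 (adjusted p = 0.105), with merging within 2.5 kb (adjusted p = 0.0664) and with 5′ ends only (adjusted p = 0.460), while the share was then lower than in other genes by the exact test (-31.6 points, adjusted p = 0.0166).

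**Figure D4:**
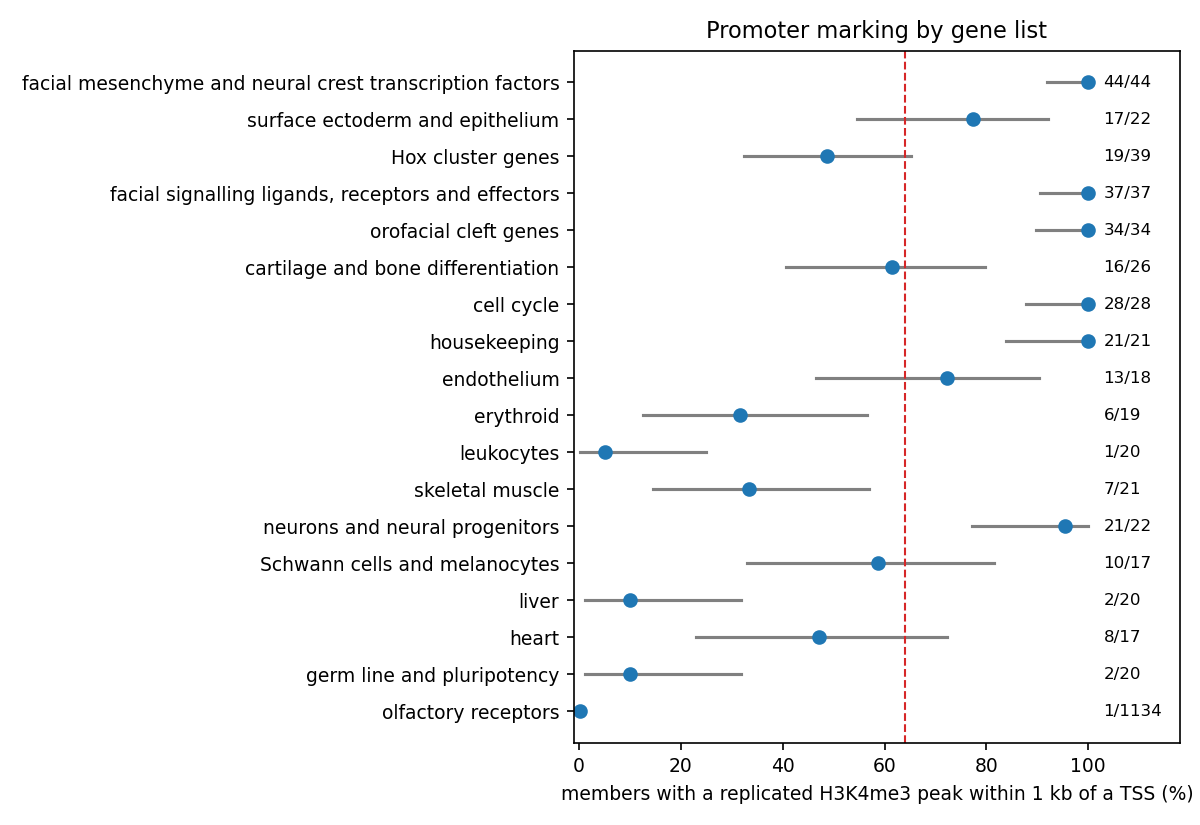
Share of members with a replicated peak within 1 kb of a TSS (points, %) in each of the 18 gene lists, with exact 95% intervals (bars), the number marked of all members at the right, and the share of all protein-coding genes, 64.0%, as a dashed line. Facial mesenchyme, signalling, cleft, cell cycle and housekeeping lists are at 100%, and leukocyte, liver, germ line and olfactory receptor lists lie at 10% or below.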

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

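The test of the number of unmatched domains after merging was chosen after the result was seen, as were the tests of the neural genes, although the CpG-matched and touching-peak widths among them were planned for every list.

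The pooled list held 3198 peaks that were not in the replicated list, a signal outside the comparisons above. Their median width was 237 bp and their median enrichment 3.06, 67.2% had −log10 q under 2, and 39.3% lay within 1 kb of a TSS. They would mark 132 further protein-coding genes, 7 of them Hox genes: Hoxa11, Hoxb3, Hoxb5, Hoxb8, Hoxc4, Hoxc10 and Hoxc13, named after their values were seen. Another 10 replicated peaks lay on unplaced or unlocalized scaffolds, where genes were assigned as on the chromosomes. The widest of these peaks had 2039 bp.

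The first pattern weighed was the width of domains at facial mesenchyme factors, whose median of 7412 bp stood apart from random lists. The CpG ratio within 1 kb of the 5′ end was argued against as the cause. In lists matched on it the upper end of the central 95% was 2268 bp. Gene length was argued against likewise, at 2194 bp in lists matched on length. CpG content over the rest of these domains was not measured, so its part in their width was not tested. With 5′ ends only, 41 of these factors were marked, so the ratio was not that of the marked promoter for all of them. Merging of nearby peaks was not the whole cause: with merging only where peaks touch, the list had 4835 bp and random lists reached 2078 bp. Neighbours that share 1 domain were not the cause either, since with each domain counted once the list had 7023 bp against an upper end of 2138 bp. Wide H3K4me3 at genes of tissue identity remains as a hypothesis. No other tissue was compared, so nothing here tests whether the width is particular to the face. The list holds transcription factors only and the random lists were not matched on gene class, so tissue and gene class cannot be told apart.

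The second pattern was the set of peaks found in 1 replicate alone. These peaks were weak, with −log10 q of at least 10 for only 34 of them in replicate 1 and 1 in replicate 2. Whether they were calls near the threshold was not decided, because the files hold no signal of the other replicate where it has no peak, and because the planned test, the overlap with −log10 q of at least 10 in both lists (91.0% in replicate 1), mostly counted other peaks: 1417 of its 1451 unmatched peaks had a partner that was filtered out. For splitting of 1 broad region into different peaks the planned test was undecided, since merging within 1 kb raised the overlap from 80.7% and 87.8% to 89.5% and 90.8%, which lay between its bounds; it was not the whole cause, because 2013 domains of replicate 1 still had no partner after merging. The lists of the replicates were derived from different numbers of further files, whose effect was not tested, and no biological explanation was tested since both replicates belong to 1 group.

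The third pattern was the wide but weakly enriched domains at neural genes, with a median of 3654 bp and a median enrichment of 12.8. The CpG ratio within 1 kb of the 5′ end was argued against as the cause of the width. The upper end of random lists matched on it was 2408 bp. CpG content over the rest of the domains was not measured. Merging of separate peaks may account for the width: with merging only where peaks touch, the median of 2137 bp lay below the upper end of 2224 bp. The enrichment was 12.8 against 41.7 in lists matched on width, below their lower end of 32.3, but 11 of 14 lists lay below their width-matched lists in permutation tests, among them facial mesenchyme (32.2 against 40.8, adjusted p = 0.0195), signalling (25.3 against 40.9, adjusted p = 7.0e-05), cleft (24.5 against 38.5, adjusted p = 3.7e-04), ectodermal (11.5 against 32.3, adjusted p = 7.0e-05), endothelial (10.8 against 35.2, adjusted p = 7.0e-05) and Hox genes (8.0 against 17.8, adjusted p = 0.00647), and only housekeeping genes lay above (54.1 against 38.9, adjusted p = 2.2e-04). Genes of the main tissue thus also lay below, though by less than the neural, ectodermal and endothelial lists, and whether these shortfalls differ was not tested. Width was matched in 10 strata with no upper bound to the widest, so the match was loose for the widest domains. In the facial mesenchyme list 38 of 44 genes lay in the widest 5%, against 13 of 37 for signalling and 7 of 21 for neural genes. The facial mesenchyme shortfall is therefore not one at equal width. The mark in a small share of the cells or at a low level, from neural tissue beside the prominences or poised promoters in mesenchyme, stays open.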

How the results depend on the processing

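The counting of each domain once and the restriction to replicated peaks that overlap both replicates' peaks were chosen after the data were seen; all other alternatives were planned. Over 45 results and 472 alternatives, 408 kept their direction and their side of the threshold or stayed within the spread between replicates, 19 changed direction, 12 newly passed a threshold, 11 lost it and 22 moved. Depth is unknown, so what it limits could not be measured. Of 1034 values for 94 named genes, 200 moved. For values that changed, the cause was not tested unless it follows from the setting.

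Calls on the facial mesenchyme, signalling, cleft and housekeeping lists held under every alternative run, although with CpG ratio as covariate their shares were only 8.8, 9.5, 11.5 and 11.4 points above those expected. The endothelial width, above random lists in the main result, lay below them with −log10 q of at least 10 (1750 bp), 5′ ends only (1760 bp), the pooled list (1900 bp), touching peaks (1550 bp) and peaks in both replicates (1814 bp), and ran from 1597 to 1874 bp with 1 replicate left out. The cartilage and bone width changed side of the random median in the pooled list (1974 bp). It did so too against CpG-matched lists and with each domain counted once (1850 bp in both). It ran from 1776 to 1888 bp with 1 replicate left out, and passed the threshold as narrower with touching peaks (1200 bp). The erythroid width changed side of the random median against CpG-matched lists (1748 bp). The endothelial share changed direction with −log10 q of at least 10 (-6.1 points). With CpG ratio as covariate, changes of direction were found for ectoderm (-2.2 points), cartilage and bone (5.1), erythroid (2.0) and Schwann and melanocyte genes (0.7), and calls were lost for cell cycle (3.2) and neural genes (8.4).

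The Hox share passed the threshold with −log10 q of at least 2 (-17.7 points) or 10 (-33.5), 5′ ends (-17.4), peaks in both replicates (-25.0) and the CpG covariate (-39.9), changed direction in the pooled list (2.1), and ran from -22.9 to -0.2 with 1 replicate left out. The Hox width lost its call with −log10 q of at least 10 (1316 bp). The difference between Hox groups lost its call with 5′ ends (499 bp), and that of their shares gained one with peaks in both replicates (47.9 points). The share of facial factors over ectoderm lost its call with 5′ ends (15.9 points). The ectodermal width ran from 1240 to 1560 bp with 1 replicate left out, and was called at the lower value.

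Neural genes lost the call of their share with −log10 q of at least 10 (15.7 points) and of their width with touching peaks (2137 bp). The heart width lost its call with −log10 q of at least 10 and with merging within 2.5 kb (1266 bp in both) and with 5′ ends (1481 bp), where the heart share passed (-31.6 points). The muscle share lost its call at 2.5 kb (-17.3 points), and the muscle width passed there (1102 bp) and with 5′ ends (1042 bp).

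The share of peaks near a TSS was 79.5% and 88.9% with −log10 q of at least 2 and 10, 75.3% and 84.7% with windows of 500 bp and 2.5 kb, 73.2% in the pooled list and 72.3 to 73.7% with 1 replicate left out. The overlap of replicates 1 and 2 was 82.3% and 95.2% with −log10 q of at least 2, 91.0% and 99.3% with at least 10, 70.9% and 72.0% with 50% of both peaks, and 89.5% and 90.8% after merging. Peaks without a partner numbered 1000 in replicate 2 with −log10 q of at least 2, 1451 and 98 with at least 10, mostly because the filter removed partners (1417 and 97 of them), 7277 and 6889 with 50% of both peaks, and 2013 and 1741 after merging.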

Other observations

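The tests of gene families were chosen after the data were seen, and the bounds for the test of CpG-rich sequence in peaks far from a TSS were set before its result.

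Gene families, taken crudely over all protein-coding genes as at least 10 symbols with the same first 3 letters and at most 1 more letter before a number, differed widely. They were not kept apart from the gene lists: of those named here, the Sox family had 10 of its 18 marked genes in a list and the keratin prefix 5 of its 53 genes. In 2-sided permutation tests of 169 families, 22 had wider and 18 narrower domains than random lists at an adjusted p under 0.05. Wide domains were found in protocadherins outside the clusters (prefix Pcd; median 4772 bp, 10 marked), the frizzled receptors of Wnt ligands (Fzd; 4766 bp, 10 marked), Sox transcription factors (Sox; 3805 bp, 18 marked) and genes with histone symbols (His; 3414 bp, 56 marked), each at an adjusted permutation p of 0.00154. Among the narrow families were sodium channels and a few other genes of the prefix Scn (939 bp, permutation test, adjusted p = 0.00260) and genes of the prefix Dna, mainly axonemal dyneins (820 bp, permutation test, adjusted p = 0.00154). Prefixes mix unrelated genes, and neighbouring histone genes can share a domain.

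Some families were marked rarely or not at all. Of 333 vomeronasal receptor genes (Vmn) 1 was marked, of 53 keratin-prefixed genes (Krt) 6, of 66 defensin-prefixed genes (Def) 2, and of 22 major urinary protein genes (Mup), 21 late cornified envelope genes (Lce) and 25 prolactin family genes (Prl) none in the replicated list. In Fisher's exact tests of 245 families, the adjusted p of these ran from 1.7e-145 for Vmn to 6.9e-09 for Lce. All 35 genes of the prefix Vps, for vacuolar protein sorting, were marked (Fisher's exact test, adjusted p = 2.1e-06). By nuclear chromosome, the share of marked protein-coding genes ran from 79.9% on chromosome 12 down to 52.7% on chromosome 7, 52.6% on chromosome 14, 50.5% on the X chromosome and 2.19% on the Y chromosome (4 of 183 genes). Among genes over 5 kb from a protein-coding TSS, 337 of 5197 lincRNA genes (6.48%) and 87 of 9110 processed pseudogenes (0.955%) were marked.

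Peaks over 10 kb from any annotated TSS included strong ones. The widest, chosen after their values were seen, had 4041 bp and an enrichment of 26.4 on chromosome 3 (96499560 to 96503600). Another of 3026 bp on chromosome 9 (67631667 to 67634692) had an enrichment of 44.8 and lay 71963 bp from the 5′ end of Tln2. A peak of 2844 bp on chromosome 1 (78215810 to 78218653) lay 18675 bp from the 5′ end of Pax3, a neural crest transcription factor gene. The hypothesis that such peaks mark CpG-rich sequence with no annotated TSS was tested against positions 20 kb away. Of 1481 such peaks on chromosomes, 21.3% had a CpG ratio of at least 0.6, against 2.23% of shifted positions (sign-flip permutation test with 20000 flips, p = 5.0e-05, the smallest they can give), and 64.8% of peaks near a TSS. This is consistent with unannotated CpG-island promoters for part of these peaks, while most had a lower ratio.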
